A study of Drosophila melanogaster with 23 samples.

How the data were processed

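The series holds 23 one-colour Affymetrix arrays of Drosophila melanogaster, each hybridised with RNA from 1 sample. Per the labels' protocols, flies were kept in 12 h light and 12 h dark, and some 50 heads of larvae or adults were dissected near Zeitgeber time 12 and dissociated with protease before GFP-positive cells were taken. Sorting was by hand, per the series' design text. The eye samples carry the same protocol text, but their label says that eyes were dissected from heads and names no sorted cell, so they were treated as whole tissue. Total RNA was isolated with the PicoPure kit, and 0.1 to 0.4 ng went through 2 rounds of T7 amplification before biotin labelling, per the labels' protocols. Such amplification shortens transcripts towards their 3' ends, and its yield can differ between genes and samples, so values of a gene are compared between groups and never between genes.

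The deposited values are log2 expression values made by the authors with GCRMA, per the submitters' processing notes. GCRMA corrects background with a model of probe sequence, normalises between arrays and summarises probes into probe sets. Its version, the settings and whether all arrays went through 1 run are not given in the sources used here. The log2 scale was read from the values, which ran from 1.68 to 16.2 with array medians between 2.90 and 3.31. GCRMA gathers undetected probe sets near 2 to 3 on this scale, so fold changes against an undetected gene depend on the background model. For that reason a log2 value of 5 was used as a limit of detection. Where a gene lay below 5 on any array of the dimmer group, the fold is given as "at least", with each value under 5 raised to 5, and where some arrays of that group lay above 5 their number is given. Differences of differences are no bounds, and are also given with values under 5 raised to 5. No genome build is given in the sources used here, so no coordinates are printed.

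Of 18952 probe sets, 183 were controls. A platform annotation table gave 13647 probe sets 1 gene, 402 several genes and 4720 no gene. Symbols of 13544 of the probe sets with 1 gene were brought up to date through the gene identifier against RefSeq's gene table of assembly Release 6 plus ISO1 MT, used for names only. The 11982 genes were each represented by the probe set with the highest mean over all arrays, a choice that mattered for the 1094 genes with more than 1 probe set. Genes above 5 on at least 2 of the 23 arrays were kept, 7670 genes (64.0%), and 4312 were left out. No probe set matched to several genes was named. All 23 columns were used.

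Samples were grouped by their titles into 8 groups, with 3 replicates each except 2 for adult small Pdf cells. The Tim samples are called GFP cells in 1 label and come from a line with a YFP reporter in another, and both labels name the same driver. No pair of arrays held the same values. The most similar pair differed by a median of 0.356 log2 units, and at most 0.404% of values were identical between any pair. No batch, scan date or slide was given in the labels used here, so none could be tested.

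Differences were tested with limma 3.58.1 in R 4.3.3, with 1 linear model of the 8 group means over all 23 arrays (residual degrees of freedom 15), moderated by eBayes, and 11 contrasts. These were 9 comparisons of a pair of groups and 2 differences of differences between adult and larval Pdf enrichment. Tests were two-sided. A gene was called where the Benjamini-Hochberg adjusted p over the 7670 genes was under 0.05 and the fold at least 2. The design, the rule for named genes, the gene lists and the alternative settings were fixed before the data were examined. In each comparison the named genes were the 10 largest rises and 6 largest falls (5 and 5 for larval Tim against Elav, adult against larval Elav and the differences of differences) among called genes whose groups did not overlap. They were ranked by the difference of means with values under 5 raised to 5. Added to these were up to 4 called members of each list that passed and of the clock, clock neuron, neuropeptide and glia lists, and Pdf, tim and Fer2 throughout. The text draws its examples from these.

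The 24 gene lists were tested with camera from limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 264 tests of all lists and comparisons. Camera asks whether the genes of a list rank higher or lower than the other genes, whereas fry, run as an alternative, asks whether they changed at all. Every list p in the text is this adjusted p, followed where it passed by the value from a correlation estimated from the data. With the preset correlation 121 of the 264 tests passed, and 27 of them also passed with the estimated one. The number of called members adjusted over the list alone is given beside each count. In 35 tests a list's median, mean and test direction differed in sign, 0 of them among those that passed. The lists were core clock feedback loop, clock kinases, phosphatases and turnover, clock neuron factors, neuropeptides, peptide processing and dense core vesicles, neuropeptide receptors, amine and metabotropic transmitter receptors, ionotropic transmitter receptors, voltage-gated, potassium and leak channels, fast transmitter and amine synthesis and transport, cAMP signalling, synaptic vesicle and pan-neuronal genes, axon guidance and adhesion, neuroblast and proliferation, ecdysone signalling, photoreceptor and phototransduction, eye pigment, glia, hemocyte, fat body, muscle, heat shock, stress and immediate early genes, oxidative phosphorylation and cytosolic ribosomal proteins. The lists of glia, hemocyte, fat body, muscle, photoreceptor, eye pigment and proliferation genes stood for other cells that a sort by hand can hold.

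The calling procedure was tested on simulated data made with the spread and means of the 7670 genes, with 50 genes changed at each size. For larval Pdf against Elav cells 2%, 12%, 34% and 58% of genes changed by 1, 1.5, 2 and 3 log2 units were recovered, with 4 false calls. For large Pdf against adult Elav cells the shares were 0%, 24%, 40% and 68% with 4 false calls, and for small Pdf cells 0%, 14%, 30% and 58% with 6. The changed genes were drawn from those above 5 in the Elav mean. The simulated comparisons made 57, 70 and 57 calls, against 1996, 695 and 671 in the real ones. The adjusted p depends on how many genes changed, so these shares can understate the recovery in the real data. A simulated gene that was not called could have changed severalfold, and the share missed in the real data was not measured.

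The alternative settings fixed beforehand were another quantile normalisation, centring of each array on its median, array weights, a stricter filter at 7 and no filter, raising values under 5 to 5, a fold of at least 4 or any fold, every probe set on its own or the mean of all probe sets, a fit of only the groups compared, the replicate number as a block, each replicate left out, an estimated correlation and fry for the lists, and eBayes with trend and robust settings. A 3' bias index per array as a covariate and a fit without the 2 arrays least correlated with their group were added after seeing the data. The index was the mean of the log2 differences between the 3' and the middle control probe sets of GAPDH and eIF4a on each array. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.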

Results

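Gene expression was measured on 23 one-colour Affymetrix arrays of Drosophila melanogaster, 1 array per sample, in 8 groups of 3 arrays except the adult small Pdf group, which had 2. The larval samples were fluorescent brain cells picked by hand from flies carrying Elav-Gal4, a driver active in neurons in general, Pdf-Gal4, active in neurons that make the clock neuropeptide PDF, Tim-Gal4, active in cells that express the clock gene timeless, or Tim-Gal4 together with Pdf-Gal80, a repressor of Gal4 in the PDF neurons. This last group is called Tim without Pdf here. The adult samples were Elav cells, large and small Pdf cells sorted by cell size, and whole dissected eyes. Heads were dissected near Zeitgeber time 12, the change from light to dark. The labels call the samples biological replicates and say nothing more of separate animals, so p-values measure the spread between these samples. The number of arrays limits the precision. Between 34.6% and 37.9% of probe sets lay above a log2 value of 5 in the group means, the level used here as the limit of detection. Replicate arrays of 1 group correlated with r between 0.846 and 0.966 across genes.

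The driver genes were measured first. Pdf stood at 14.83 ± 0.43 on the log2 scale in larval Pdf cells and at 14.34 ± 0.17 in larval Tim cells (SD, n = 3 each), against 2.96 ± 0.065 in larval Elav cells. With Pdf-Gal80 in the line the level was 2.92 ± 0.14, below the limit of detection on all 3 arrays. In adults it stood at 15.35 ± 0.57 in large Pdf cells (n = 3) and 15.53 ± 0.054 in small Pdf cells (n = 2), against 3.85 ± 1.42 in adult Elav cells and 3.05 ± 0.033 in the eye. The neuronal gene elav was high in the sorted cells and in the eye alike, at 11.55 ± 1.24 in larval Elav, 12.44 ± 0.24 in larval Pdf, 12.88 ± 0.13 in adult Elav cells and 12.22 ± 0.65 in the eye. The clock gene tim was detected in every group but larval Elav cells, with means of 13.70 ± 0.32 in larval Pdf, 10.69 ± 0.65 in larval Tim, 10.20 ± 0.15 in Tim without Pdf, 14.07 ± 0.15 in large Pdf and 14.95 ± 0.021 in small Pdf cells.

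**Figure D1:**
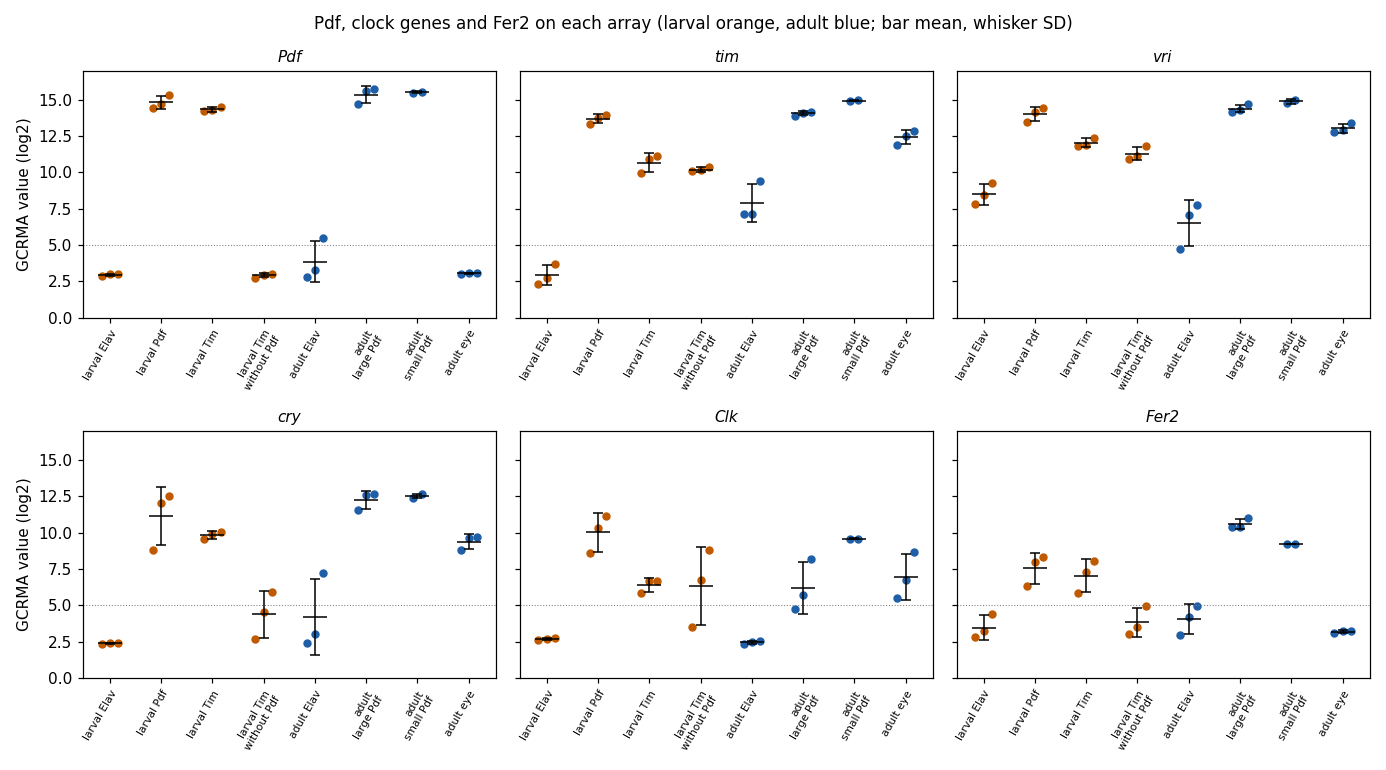
Log2 expression (vertical axis, GCRMA values) of Pdf, tim, vri, cry, Clk and Fer2 in the 8 groups (horizontal axis, larval orange, adult blue). Each point is 1 array, the bar is the group mean, the whisker the SD and the dotted line the limit of detection at 5. Pdf is above 14 in the larval Pdf, larval Tim and both adult Pdf groups and below 5 in the group with Pdf-Gal80.

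Larval Pdf cells were compared with larval Elav cells, taken as the reference for neurons in general. In larval Elav cells synaptic vesicle and pan-neuronal genes had a median of 5.09, channels of 3.31 and proliferation genes of 12.14. In adult Elav cells these medians were 12.75, 9.16 and 3.92, so the larval reference was low in neuronal genes. Differences from it can come from the reference as well as from PDF neurons. Pdf was at least 910.2-fold higher in Pdf cells (adjusted p = 9.12e-12). All 8 members of the core clock feedback loop, the transcription factors and repressors that drive the circadian oscillation, were called higher (adjusted p = 1.06e-10, and adjusted p = 0.00611 with an estimated correlation; 8 adjusted over the list alone). The clock repressor tim was at least 416-fold higher at 13.70 ± 0.32, the blue-light photoreceptor cry at least 71.1-fold at 11.15 ± 2.02, the activator Clk at least 32.4-fold at 10.02 ± 1.31, and the repressor per at least 26.1-fold at 9.71 ± 0.75 (SD, n = 3). Fer2, which encodes a basic helix-loop-helix protein of clock neurons, was at least 5.87-fold higher (adjusted p = 1.38e-04). Fer2 was picked out by the study from these samples, so its enrichment here is not independent evidence. The clock neuron factors had 4 higher, 0 lower and 9 not called of 13 measured (adjusted p = 0.00294, and adjusted p = 0.109 with an estimated correlation; 4 higher adjusted over the list alone), among them the PDF receptor gene Pdfr (7.27 against 2.36, at least 4.84-fold higher). Of the clock kinases, phosphatases and turnover factors 0 of 7 were called, and 0 adjusted over the list alone (adjusted p = 0.631).

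Genes of peptide secretion were also higher in larval Pdf cells. Of the peptide processing and dense core vesicle list 9 of 10 were called higher (adjusted p = 6.44e-06, and adjusted p = 0.0351 with an estimated correlation; 9 adjusted over the list alone). The prohormone convertase helper 7B2 was 245-fold higher, and the amidating enzyme gene Pal2 was at least 181-fold higher, with 1 of 3 larval Elav arrays above 5. Of the neuropeptides 3 of 22 were called higher, and 2 adjusted over the list alone (adjusted p = 0.0742). The voltage-gated, potassium and leak channels had 16 of 25 higher (adjusted p = 3.62e-10, and adjusted p = 0.0806 with an estimated correlation; 16 adjusted over the list alone), with the calcium-activated potassium channel SK at least 92.2-fold and the inward rectifier Irk1 at least 40.1-fold higher. The ionotropic transmitter receptors had 11 of 15 higher (adjusted p = 3.94e-06, and adjusted p = 0.128 with an estimated correlation; 11 adjusted over the list alone), with the acetylcholine receptor subunit nAChRalpha2 at least 14.0-fold higher. The synaptic vesicle and pan-neuronal genes had 13 of 17 higher (adjusted p = 1.27e-09, and adjusted p = 0.0662 with an estimated correlation; 13 adjusted over the list alone), with the active zone gene Rim at least 87.9-fold higher. The cAMP signalling genes had 9 of 11 higher (adjusted p = 5.80e-05, and adjusted p = 0.0498 with an estimated correlation; 9 adjusted over the list alone), with the adenylyl cyclase Ac78C at least 8.88-fold higher. The proliferation genes moved the other way in the same comparison, with a median log2 difference of -3.04.

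Smaller parts of other neuronal lists were called higher. The neuropeptide receptors had 4 of 13 (adjusted p = 0.00920, and adjusted p = 0.280 with an estimated correlation; 5 adjusted over the list alone), with sNPF-R at least 20.5-fold and NPFR at least 14.5-fold higher. The amine and metabotropic transmitter receptors had 3 of 12 (adjusted p = 0.00228, and adjusted p = 0.197 with an estimated correlation; 4 adjusted over the list alone), with the dopamine and ecdysteroid receptor DopEcR at least 73.4-fold and the serotonin receptor 5-HT1A at least 61.7-fold higher. Fast transmitter and amine synthesis and transport had 5 of 14 (adjusted p = 0.00655, and adjusted p = 0.0892 with an estimated correlation; 5 adjusted over the list alone), and its test ended at adjusted p = 0.0661 once values under 5 were raised to 5. Axon guidance and adhesion had 3 of 20 (adjusted p = 0.0379, and adjusted p = 0.347 with an estimated correlation; 3 adjusted over the list alone). That last test was lost without larval Elav replicate 2 (0.120), larval Pdf replicate 2 (0.0763) or larval Pdf replicate 3 (0.0669), after another quantile normalisation (0.0707) and with values under 5 raised to 5 (0.0527). The photoreceptor and phototransduction list had 7 higher and 1 lower of 20 (adjusted p = 0.00195, and adjusted p = 0.206 with an estimated correlation; 7 higher and 1 lower adjusted over the list alone). Its members that were higher included cpo, an RNA-binding protein of neurons (at least 43.0-fold, with 2 of 3 larval Elav arrays above 5), and the phosphatase rdgC (at least 4.40-fold). Heat shock, stress and immediate early genes had 6 of 11 higher (adjusted p = 8.41e-04, and adjusted p = 0.102 with an estimated correlation; 6 adjusted over the list alone), with the co-chaperone stv at least 65.5-fold higher. Outside the lists, the uncharacterised genes CG4577 (at least 242-fold), CG2269 (at least 240.1-fold) and CG12290 (at least 196-fold) were among the largest rises.

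Genes of dividing cells were lower in larval Pdf than in larval Elav cells. Of the neuroblast and proliferation list 14 of 20 were called lower (adjusted p = 1.58e-08, and adjusted p = 0.102 with an estimated correlation; 19 adjusted over the list alone), including the cyclin CycB3 (26.1-fold lower) and the neuroblast factor ase (at least 14.5-fold, with 1 of 3 larval Pdf arrays above 5). The largest falls of named genes were the peroxisomal import gene Pex7 (at least 75.1-fold, with 1 of 3 larval Pdf arrays above 5), CG12496 (at least 72.8-fold, with 1 of 3 larval Pdf arrays above 5), CG14545 (at least 56.3-fold) and CG9993 (at least 50.1-fold). Markers of other cells moved with the Pdf group. Of the glial genes 7 of 14 were called higher (adjusted p = 0.00195, and adjusted p = 0.0854 with an estimated correlation; 7 adjusted over the list alone), with glutamine synthetase Gs2 at 11.85 ± 1.13 against 4.24 ± 1.27, and the astrocyte gene alrm at least 16.7-fold higher. Of the hemocyte genes 5 of 11 were higher (adjusted p = 0.00295, and adjusted p = 0.285 with an estimated correlation; 8 adjusted over the list alone), with Hml at 11.91, 9.69 and 2.14 and He at 9.94, 9.56 and 2.31 on the 3 Pdf arrays.

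The tests of the remaining lists did not pass for larval Pdf against Elav cells. Ecdysone signalling had 3 higher, 2 lower and 9 not called (adjusted p = 0.241; 3 and 2 adjusted over the list alone), and eye pigment genes had 1 higher, 1 lower and 11 not called (adjusted p = 0.987; 1 and 1 adjusted over the list alone). Fat body genes had 1 higher, 0 lower and 7 not called (adjusted p = 0.390; 1 and 0), and muscle genes 0 higher, 0 lower and 13 not called (adjusted p = 0.0963; 0 and 0). Oxidative phosphorylation had 0 higher, 2 lower and 25 not called (adjusted p = 0.0674; 0 and 0), and cytosolic ribosomal proteins 0 higher, 0 lower and 33 not called (adjusted p = 0.226; 0 and 0). In total 1996 of 7670 genes were called, 1017 higher and 979 lower, and over all 7670 genes the groups did not overlap in 2867, where chance gives 10%. Lower calls outnumbered higher ones with array weights and without larval Elav replicate 1, among other settings. Without larval Elav replicate 2 the count was 1294, and with only the groups compared in the fit it was 1173.

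**Figure D2:**
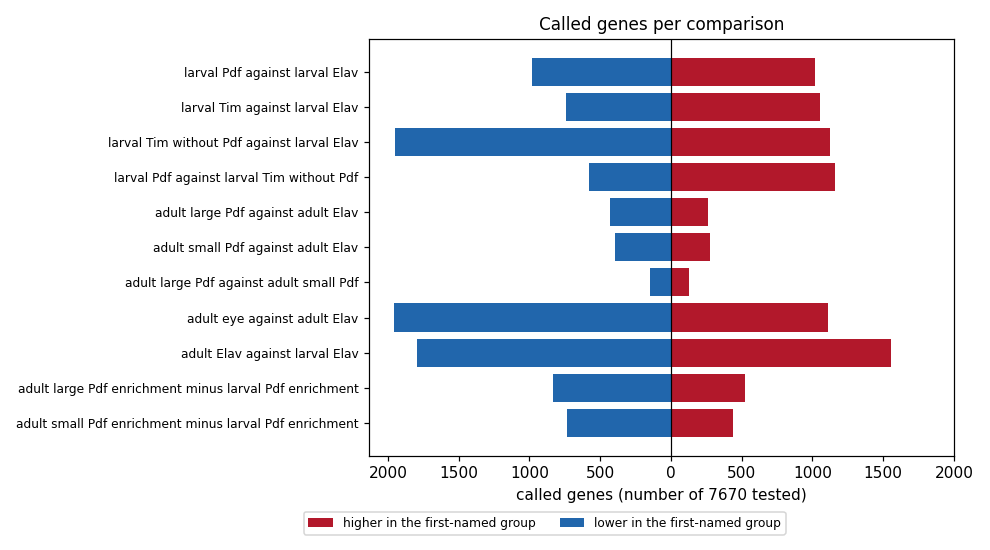
Called genes (horizontal axis, number of 7670 tested) in the 11 comparisons (vertical axis), with genes higher in the first-named group as red bars to the right and lower ones as blue bars to the left of 0. The bars reach from 278 calls between the adult Pdf groups to 3352 between adult and larval Elav cells.

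Larval Tim cells, which include the PDF neurons, were compared with the same Elav cells. Pdf was at least 649-fold higher at 14.34 ± 0.17 (SD, n = 3), the eclosion hormone gene Eh at least 466-fold at 13.86 ± 0.98, and jhamt, the juvenile hormone acid methyltransferase, at least 160.4-fold at 12.33 ± 2.41. All 8 core clock genes were called higher (adjusted p = 6.65e-08, and adjusted p = 0.0192 with an estimated correlation; 8 adjusted over the list alone), with tim at least 51.5-fold and cry at least 28.8-fold. Fer2 was at least 4.15-fold higher (adjusted p = 5.25e-04). Neuropeptides had 11 of 22 higher (adjusted p = 1.89e-07, and adjusted p = 0.0123 with an estimated correlation; 12 adjusted over the list alone), including AstC (at least 149-fold, 12.22 ± 0.88), Dh31 (at least 114-fold, 11.83 ± 1.71) and CCHa1 (at least 44.2-fold). Peptide processing and dense core vesicles had 7 of 10 higher (adjusted p = 6.68e-06, and adjusted p = 0.0351 with an estimated correlation; 8 adjusted over the list alone). Fast transmitter and amine synthesis and transport had 6 of 14 higher (adjusted p = 5.47e-04, and adjusted p = 0.0459 with an estimated correlation; 8 adjusted over the list alone), with the choline transporter ChT at least 41.7-fold and the vesicular monoamine transporter Vmat at least 18.3-fold. Glial genes were higher along with them, as 7 of 14 were called (adjusted p = 5.79e-05, and adjusted p = 0.0351 with an estimated correlation; 7 adjusted over the list alone), with the glial factor repo at 9.28 ± 0.63 (at least 19.4-fold) and the midline glia gene wrapper at least 8.52-fold higher.

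Several lists passed in larval Tim cells with the preset correlation alone. Clock neuron factors had 6 of 13 higher (adjusted p = 6.70e-04, and adjusted p = 0.0854 with an estimated correlation; 6 higher and 1 lower adjusted over the list alone). Synaptic vesicle and pan-neuronal genes had 14 of 17 (adjusted p = 1.27e-09, and adjusted p = 0.0662 with an estimated correlation; 15 adjusted over the list alone), and channels 13 of 25 (adjusted p = 2.61e-08, and adjusted p = 0.103 with an estimated correlation; 13 adjusted over the list alone). Amine and metabotropic receptors had 7 of 12 (adjusted p = 2.44e-05, and adjusted p = 0.0892 with an estimated correlation; 8 adjusted over the list alone), with Octbeta1R at least 23.3-fold and Dop2R at least 13.2-fold higher. The neuroblast and proliferation list had 15 of 20 lower (adjusted p = 2.30e-08, and adjusted p = 0.103 with an estimated correlation; 18 adjusted over the list alone), with the neuroblast gene dpn at 6.29 ± 2.17 against 10.75 ± 0.56. Of the hemocyte genes 2 of 11 were higher (adjusted p = 0.408; 0 adjusted over the list alone). Axon guidance and adhesion had 4 of 20 higher (adjusted p = 0.0168, and adjusted p = 0.280 with an estimated correlation; 4 adjusted over the list alone), and the test was lost without larval Elav replicate 2 (0.0694) or larval Tim replicate 3 (0.0714). The comparison called 1795 genes, 1056 higher and 739 lower, and over all genes the groups did not overlap in 3097, where chance gives 10%. With array weights the count was 3402. The share of higher calls was 58.8%, but 47.4% with array weights, 51.7% after another quantile normalisation and 51.4% with values under 5 raised to 5.

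In larval Tim cells without the PDF neurons, the nocturnin homologue cu was at least 594-fold higher than in Elav cells, and several genes of hormone synthesis were among the largest rises, though no list of such genes was tested. The juvenile hormone enzyme jhamt was at least 526-fold higher at 14.04 ± 0.28 (SD, n = 3), and the ecdysteroid synthesis genes sad and spok were at least 318-fold and at least 226-fold higher at 13.31 ± 0.14 and 12.82 ± 0.27. In larval Elav cells jhamt lay at 2.37 ± 0.021, and in larval Pdf cells at 2.35 ± 0.027. GstE14, another gene of ecdysteroid synthesis, was at least 198-fold higher. Pdf lay below 5 in both groups (2.92 ± 0.14 and 2.96 ± 0.065). Core clock genes had 6 of 8 higher (adjusted p = 2.44e-05, and adjusted p = 0.0505 with an estimated correlation; 6 adjusted over the list alone), with tim at least 36.7-fold and the repressor cwo 13.3-fold higher. Fer2 stood at 3.83 ± 1.00 (adjusted p = 0.725, not called). All 20 neuroblast and proliferation genes were lower (adjusted p = 4.40e-12, and adjusted p = 0.0556 with an estimated correlation; 20 adjusted over the list alone), with the cyclin CycB at least 277-fold, the chromosomal passenger Incenp at least 147-fold and the neuroblast gene dpn at least 53.9-fold lower.

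Other lists in these cells passed with the preset correlation alone. Ecdysone signalling had 5 higher and 2 lower of 14 (adjusted p = 0.00655, and adjusted p = 0.0854 with an estimated correlation; 6 higher and 2 lower adjusted over the list alone), with the receptor EcR 4.78-fold and its target Hr3 at least 5.76-fold higher. Synaptic vesicle and pan-neuronal genes had 8 of 17 higher (adjusted p = 1.17e-04, and adjusted p = 0.210 with an estimated correlation; 8 adjusted over the list alone), with Snap25 at least 66.0-fold. The cAMP list had 5 of 11 higher (adjusted p = 0.00368, and adjusted p = 0.112 with an estimated correlation; 5 adjusted over the list alone), with the adenylyl cyclase Ac76E at least 56.0-fold. Heat shock, stress and immediate early genes had 4 of 11 higher (adjusted p = 0.00874, and adjusted p = 0.194 with an estimated correlation; 4 adjusted over the list alone), with stv at least 41.3-fold and the AP-1 subunit kay 22.1-fold. Neuropeptides had 5 of 22 higher (adjusted p = 0.0143, and adjusted p = 0.157 with an estimated correlation; 5 adjusted over the list alone), with ITP at least 30.8-fold higher, and the test was lost after another quantile normalisation (0.0644). Glial genes had 2 of 14 higher (adjusted p = 0.0750; 2 adjusted over the list alone), with the blood-brain barrier receptor moody at least 60.6-fold. An index of 3' bias, which compares 3' with middle control probe sets, averaged 3.43 ± 0.33 on these arrays (SD, n = 3) and 1.70 ± 0.45 on the larval Elav arrays. The comparison called 3075 genes, 1126 higher and 1949 lower (36.6% higher), and over all genes the groups did not overlap in 3873, where chance gives 10%. The share of higher calls was 55.7% with each array centred on its median, which moved the median of all genes from -0.23 to 0.35, and 43.4% after another quantile normalisation. The count was 1604 with a 3' bias index in the fit, an alternative added after seeing the data.

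The 2 larval groups with and without PDF neurons were also compared directly. Pdf was at least 910.2-fold higher in Pdf cells (adjusted p = 8.50e-12), and tim was 11.3-fold higher, at 13.70 ± 0.32 against 10.20 ± 0.15 (SD, n = 3). The clock genes cry (11.15 ± 2.02 against 4.39 ± 1.62) and per (9.71 ± 0.75 against 4.74 ± 1.90) were higher too, each above 5 on 1 of the 3 arrays without Pdf, and Fer2 was at least 5.87-fold higher. Core clock genes had 6 of 8 higher (adjusted p = 3.91e-04, and adjusted p = 0.0858 with an estimated correlation; 7 adjusted over the list alone). The genes jhamt, sad and spok were at least 526-fold, at least 318-fold and at least 226-fold lower in Pdf cells. The channels had 11 of 25 higher (adjusted p = 0.00228, and adjusted p = 0.384 with an estimated correlation; 13 adjusted over the list alone), with Irk1 at 10.33 ± 0.84 against 3.99 ± 1.11 and unc80 at least 6.74-fold higher. Neuroblast and proliferation genes had 12 of 20 higher in Pdf cells (adjusted p = 9.19e-06, and adjusted p = 0.197 with an estimated correlation; 13 adjusted over the list alone), with Incenp at 10.72 ± 0.78 against 3.27 ± 0.80. Glial alrm (at least 16.7-fold) was higher too, while the glial list had 4 higher, 2 lower and 8 not called (adjusted p = 0.640; 5 higher and 2 lower adjusted over the list alone).

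Synaptic vesicle and pan-neuronal genes had 9 higher and 1 lower of 17 in this direct comparison (adjusted p = 0.0409, and adjusted p = 0.529 with an estimated correlation; 10 and 1 adjusted over the list alone). The test was lost after another quantile normalisation (0.0519) and without larval Pdf replicate 2 (0.0960) or 3 (0.0734) or Tim without Pdf replicate 1 (0.0692) or 3 (0.136). Ecdysone signalling had 2 higher and 4 lower of 14 (adjusted p = 0.0434, and adjusted p = 0.172 with an estimated correlation; 2 and 4 adjusted over the list alone), with the nuclear receptor Hr51 at least 32.0-fold higher and Eip63E 20.5-fold lower. This test was lost after another quantile normalisation (0.0552) and with the replicate number as a block (0.0526). It was also lost without larval Pdf replicate 1 (0.0906) or 3 (0.0682) or Tim without Pdf replicate 2 (0.0741) or 3 (0.101). In total 1740 genes were called, 1160 higher and 580 lower (66.7% higher), and over all genes the groups did not overlap in 2848, where chance gives 10%. The share of higher calls was 40.5% with each array centred on its median and 54.2% after another quantile normalisation, and the count was 1145 without Tim without Pdf replicate 3. It was 868 with only the groups compared and 719 with the 3' bias index, an alternative added after seeing the data.

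**Figure D3:**
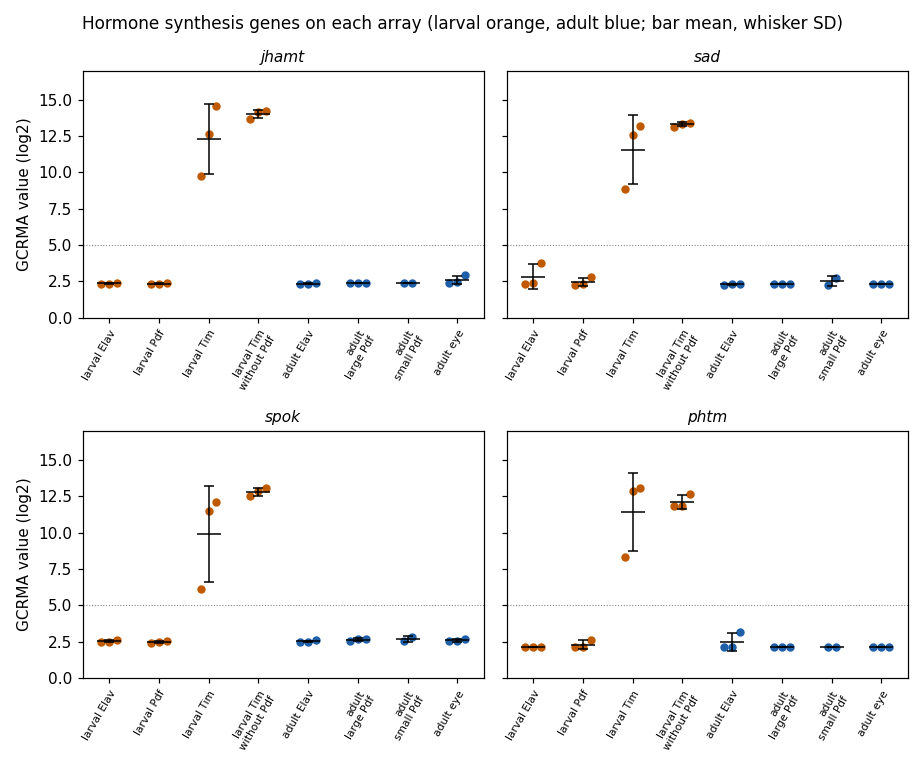
Log2 expression (vertical axis, GCRMA values) of jhamt, sad, spok and phtm in the 8 groups (horizontal axis, larval orange, adult blue). Each point is 1 array, the bar is the group mean, the whisker the SD and the dotted line the limit of detection at 5. All 4 genes are above 12 in the mean of Tim without Pdf and below 3 in the means of larval Elav and larval Pdf cells.

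Adult large Pdf cells were compared with adult Elav cells. Pdf was at least 1175-fold higher, with 1 of 3 adult Elav arrays above 5 (adjusted p = 1.30e-11), and core clock genes had 7 of 8 higher (adjusted p = 3.02e-11, and adjusted p = 0.00564 with an estimated correlation; 7 adjusted over the list alone). The repressor vri stood at 14.39 ± 0.26 against 6.53 ± 1.59 (SD, n = 3), tim was 71.2-fold and per 23.6-fold higher. Fer2 was at least 48.7-fold higher at 10.61 ± 0.37 (adjusted p = 1.23e-06), under the same limit of having been picked from these samples. CG17777 (at least 55.8-fold) and the cuticle protein gene Cpr60D (at least 38.1-fold) were among the largest rises.

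Transmitter and peptide genes were lower in large Pdf cells. Fast transmitter and amine synthesis and transport had 8 lower and 1 higher of 14 (adjusted p = 9.70e-08, and adjusted p = 0.00564 with an estimated correlation; 9 lower and 1 higher adjusted over the list alone). The vesicular monoamine transporter Vmat was at least 1281-fold lower, below 5 on all large Pdf arrays against 15.32 ± 0.041 in Elav cells, and the GABA synthesis gene Gad1 was at least 550.0-fold lower. Neuropeptides had 10 lower and 2 higher of 22 (adjusted p = 4.07e-06, and adjusted p = 0.0206 with an estimated correlation; 12 lower and 2 higher adjusted over the list alone), with ITP at least 439-fold, FMRFa at least 267-fold and Ms 242-fold lower. Amine and metabotropic receptors had 6 of 12 lower (adjusted p = 1.35e-05, and adjusted p = 0.0854 with an estimated correlation; 7 adjusted over the list alone), with mAChR-B at least 37.3-fold lower. Oxidative phosphorylation had 1 of 27 lower (adjusted p = 0.00157, and adjusted p = 0.403 with an estimated correlation; 0 adjusted over the list alone). Cytosolic ribosomal proteins had 1 of 33 higher (adjusted p = 0.00280, and adjusted p = 0.510 with an estimated correlation; 0 adjusted over the list alone), and this test was lost without large Pdf replicate 1 (0.0749). Glial genes had 0 higher, 0 lower and 14 not called (adjusted p = 0.556; 0 and 0 adjusted over the list alone), with repo at 4.59 ± 1.40 against 3.34 ± 0.0087 (adjusted p = 0.352). The clock neuron factors had 2 higher, 3 lower and 8 not called (adjusted p = 0.302; 2 and 4 adjusted over the list alone). The comparison called 695 genes, 261 higher and 434 lower (37.6% higher), and over all genes the groups did not overlap in 2072, where chance gives 10%. The share of higher calls was 55.2% with each array centred on its median, which moved the median of all genes from -0.07 to 0.23, and 47.2% after another quantile normalisation. The count was 426 with only the groups compared.

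Adult small Pdf cells, with 2 arrays, were compared with the same Elav cells. Pdf was at least 1328-fold higher, with 1 of 3 adult Elav arrays above 5. The clock gene tim was 131-fold higher at 14.95 ± 0.021 (SD, n = 2), and Clk at least 24.3-fold at 9.60 ± 0.0042. Core clock genes had 7 of 8 higher (adjusted p = 4.40e-12, and adjusted p = 0.00564 with an estimated correlation; 7 adjusted over the list alone). Fer2 was at least 18.5-fold higher (adjusted p = 1.06e-04), again not as independent evidence. The uncharacterised genes CG31675 (at least 97.1-fold) and CG13054 (43.0-fold) were among the largest rises. Of the genes of fast transmitter and amine synthesis and transport 9 of 14 were lower (adjusted p = 7.99e-09, and adjusted p = 0.00564 with an estimated correlation; 11 adjusted over the list alone), with Gad1 at least 550.0-fold and the tyrosine hydroxylase gene ple at least 33.2-fold lower. Neuropeptides had 9 lower and 1 higher of 22 (adjusted p = 3.52e-05, and adjusted p = 0.0351 with an estimated correlation; 10 lower and 1 higher adjusted over the list alone), with Mip at least 558-fold and FMRFa at least 267-fold lower. Amine and metabotropic receptors had 3 of 12 lower (adjusted p = 0.0194, and adjusted p = 0.329 with an estimated correlation; 5 lower and 1 higher adjusted over the list alone). Oxidative phosphorylation had 5 of 27 lower (adjusted p = 4.14e-07, and adjusted p = 0.172 with an estimated correlation; 15 adjusted over the list alone). The comparison called 671 genes, 274 higher and 397 lower (40.8% higher), and over all genes the groups did not overlap in 3036, where chance gives 20%. The share of higher calls was 51.4% with each array centred on its median (median of all genes -0.05, and 0.17 when centred) and 47.0% after another quantile normalisation. The count was 408 without small Pdf replicate 1 and 352 with only the groups compared.

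Large and small Pdf cells were compared with each other. The short neuropeptide F gene sNPF was lower in large cells, at 4.65 ± 1.13 against 9.12 ± 0.33 (SD, n = 3 and 2; adjusted p = 3.53e-04), and Pdfr lay at 2.44 ± 0.12 against 6.59 ± 0.73 (at least 3.02-fold lower). The Pdfr call was lost with values under 5 raised to 5 (adjusted p = 0.108). CG9338 (at least 60.1-fold), CG31675 (at least 97.1-fold) and the synaptic Arc1 gene (112-fold) were also lower in large cells, and CG9171 (at least 48.0-fold), CG18467 (at least 30.2-fold) and CG5968 (24.7-fold) higher. Pdf (log2 difference -0.18, SE 0.56), tim (-0.88, SE 0.59) and Fer2 (1.40, SE 0.74) were not called. Clock neuron factors had 2 of 13 lower (adjusted p = 0.0143, and adjusted p = 0.191 with an estimated correlation; 3 adjusted over the list alone), and the test was lost without small Pdf replicate 2 (0.0619) and with values under 5 raised to 5 (0.0661). Core clock genes had 0 higher, 0 lower and 8 not called (adjusted p = 0.133; 0 and 0 adjusted over the list alone), with Clk at 6.22 ± 1.79 against 9.60 ± 0.0042 (adjusted p = 0.131). Oxidative phosphorylation passed with 0 of 27 members called (adjusted p = 0.00779, and adjusted p = 0.491 with an estimated correlation; 0 adjusted over the list alone) and a median difference of 0.51, and was lost without small Pdf replicate 2 (0.0926). In total 278 genes were called, 131 higher and 147 lower in large cells, and over all genes the groups did not overlap in 2364, where chance gives 20%. Without large Pdf replicate 2 higher calls outnumbered lower ones (55.1% higher), as they did without small Pdf replicate 1 (54.3%) or 2 (50.2%). With only the groups compared in the fit the count was 19.

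The dissected eye was compared with adult Elav cells. Phototransduction genes were highest, with the arrestins Arr1 (14.76 ± 0.17 against 2.24 ± 0.0098, at least 867-fold, SD, n = 3) and Arr2 (at least 761-fold) and the phototransduction channel trp (at least 746-fold). The photoreceptor list had 14 higher and 1 lower of 20 (adjusted p = 4.40e-12, and adjusted p = 0.0181 with an estimated correlation; 15 higher and 2 lower adjusted over the list alone). Core clock genes had 5 of 8 higher (adjusted p = 8.84e-04, and adjusted p = 0.100 with an estimated correlation; 5 adjusted over the list alone), with tim at 12.44 ± 0.49 against 7.92 ± 1.31. Pdf and Fer2 were not called (adjusted p = 0.217 and 0.316). The fast transmitter and amine synthesis and transport list had 10 lower and 1 higher of 14 (adjusted p = 5.98e-04, and adjusted p = 0.0462 with an estimated correlation; 10 lower and 1 higher adjusted over the list alone), with the octopamine synthesis genes Tdc2 at least 64.3-fold and Tbh at least 66.2-fold lower. Neuropeptides had 14 of 22 lower (adjusted p = 2.16e-04, and adjusted p = 0.0505 with an estimated correlation; 14 adjusted over the list alone), with FMRFa at least 267-fold and sNPF at least 227-fold. Neuropeptide receptors had 10 lower and 1 higher of 13 (adjusted p = 0.0101, and adjusted p = 0.285 with an estimated correlation; 10 and 1 adjusted over the list alone), and amine and metabotropic receptors 9 of 12 lower (adjusted p = 0.00580, and adjusted p = 0.255 with an estimated correlation; 9 adjusted over the list alone).

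Markers of other tissues were high in the eye, which was dissected and not sorted. Fat body genes had 7 of 8 higher (adjusted p = 2.07e-06, and adjusted p = 0.0192 with an estimated correlation; 7 adjusted over the list alone), with the yolk protein genes Yp3 at least 516-fold and Yp2 at least 168-fold. Muscle genes had 10 of 13 higher (adjusted p = 8.99e-06, and adjusted p = 0.0192 with an estimated correlation; 11 adjusted over the list alone), with Mf at least 12.4-fold and Mlc1 at least 6.03-fold. Glial genes had 10 of 14 higher (adjusted p = 3.52e-05, and adjusted p = 0.0351 with an estimated correlation; 10 adjusted over the list alone), with moody at least 78.9-fold and the barrier transporter Mdr65 at least 11.9-fold. Hemocyte genes had 6 higher and 2 lower of 11 (adjusted p = 0.0327, and adjusted p = 0.466 with an estimated correlation; 6 and 2 adjusted over the list alone). The hemocyte test was lost without eye replicate 3 (0.0591) or adult Elav replicate 2 (0.0513), after another quantile normalisation (0.0722) and with values under 5 raised to 5 (0.0974). Eye pigment genes had 5 higher, 4 lower and 4 not called (adjusted p = 0.0674; 5 and 5 adjusted over the list alone). Ionotropic receptors had 9 lower and 2 higher of 15 (adjusted p = 0.0162, and adjusted p = 0.457 with an estimated correlation; 10 and 2 adjusted over the list alone), lost without eye replicate 3 (0.0914). Oxidative phosphorylation had 14 of 27 lower (adjusted p = 0.00874, and adjusted p = 0.497 with an estimated correlation; 14 adjusted over the list alone), with RFeSP 4.38-fold and COX5A 4.29-fold lower. The 3' bias index averaged 3.92 ± 0.48 on the eye arrays (SD, n = 3) and 2.42 ± 0.20 on the adult Elav arrays. The comparison called 3063 genes, 1107 higher and 1956 lower (36.1% higher), and over all genes the groups did not overlap in 4322, where chance gives 10%. The share of higher calls was 54.0% with each array centred on its median, which moved the median of all genes from -0.50 to 0.07, and 46.5% after another quantile normalisation. The count was 1577 with the 3' bias index in the fit, an alternative added after seeing the data.

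**Figure D4:**
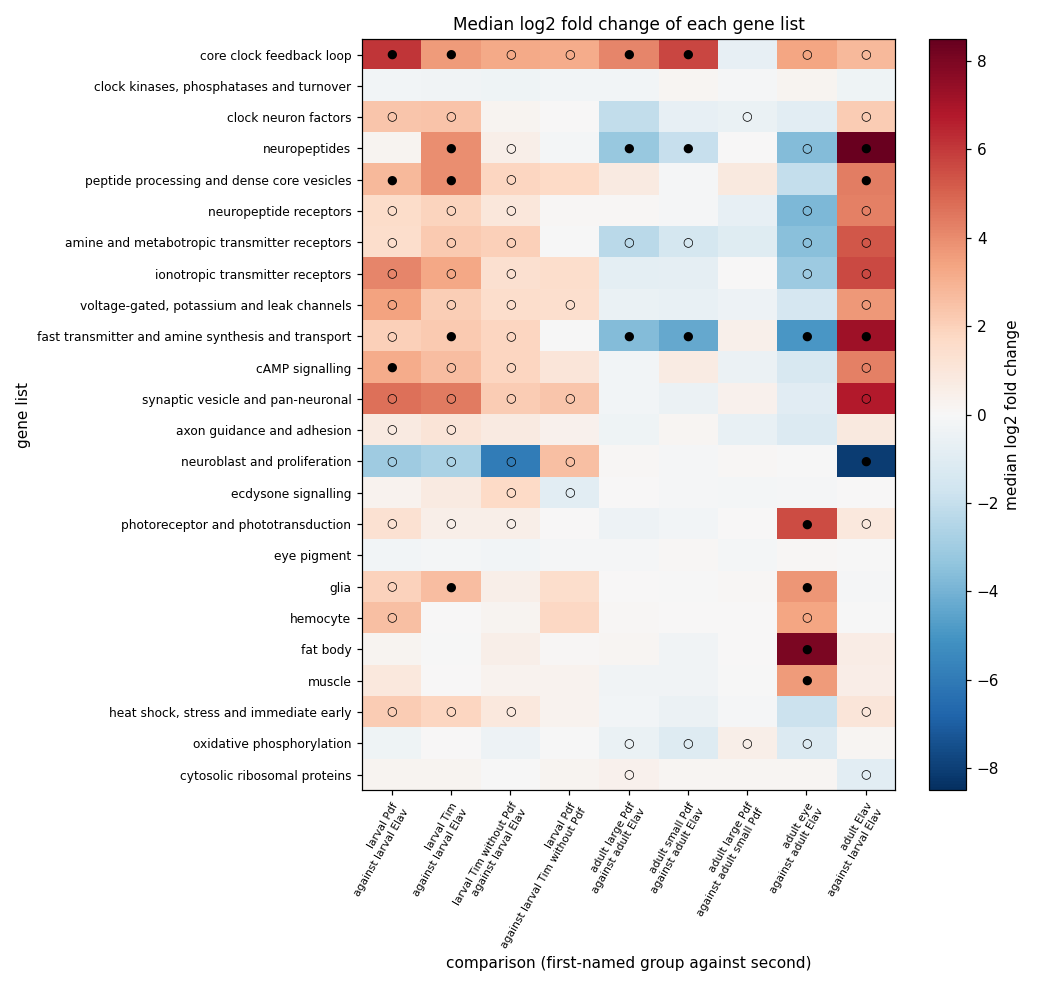
Median log2 fold change (colour) of the 24 gene lists (vertical axis) in the 9 comparisons of a pair of groups (horizontal axis). A filled dot marks a list that passed camera at adjusted p under 0.05 with the preset and with an estimated correlation, and an open dot one that passed with the preset correlation alone. Proliferation genes are lowest in adult against larval Elav cells, at a median of -8.08 (-6.65 with values under 5 raised to 5).

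Adult and larval Elav cells differed in the genes of neuronal function and of cell division. The neuropeptide gene Ms rose from 2.57 ± 0.14 in larvae to 15.80 ± 0.09 in adults (at least 1778-fold; SD, n = 3), Vmat from 3.17 ± 0.74 to 15.32 ± 0.041 (at least 1281-fold), and NPF was at least 599-fold higher in adults. Neuropeptides had 15 of 22 higher (adjusted p = 1.27e-07, and adjusted p = 0.0121 with an estimated correlation; 15 adjusted over the list alone), and peptide processing all 10 (adjusted p = 4.15e-06, and adjusted p = 0.0351 with an estimated correlation; 10 adjusted over the list alone). Of the genes of fast transmitter and amine synthesis and transport 13 of 14 were higher (adjusted p = 2.01e-09, and adjusted p = 0.00564 with an estimated correlation; 13 adjusted over the list alone), with Gad1 at least 550.0-fold and the serotonin transporter SerT at least 192-fold. All 20 neuroblast and proliferation genes were lower in adults (adjusted p = 5.93e-15, and adjusted p = 0.0351 with an estimated correlation; 20 adjusted over the list alone), with the replication genes Mcm2 at least 159-fold and PCNA at least 155-fold lower.

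More neuronal lists were higher in adult Elav cells with the preset correlation alone. All 17 synaptic vesicle and pan-neuronal genes were higher (adjusted p = 3.74e-10, and adjusted p = 0.0602 with an estimated correlation; 17 adjusted over the list alone), with Snap25 at least 178-fold and Rim at least 116-fold. Channels had 21 of 25 higher (adjusted p = 3.62e-10, and adjusted p = 0.0806 with an estimated correlation; 23 adjusted over the list alone), with SK at least 121-fold, and all 12 amine and metabotropic receptors were higher (adjusted p = 3.66e-07, and adjusted p = 0.0505 with an estimated correlation; 12 adjusted over the list alone). Neuropeptide receptors had 11 of 13 (adjusted p = 1.95e-05, and adjusted p = 0.0864 with an estimated correlation; 11 adjusted over the list alone), and ionotropic receptors 12 of 15 (adjusted p = 1.07e-06, and adjusted p = 0.110 with an estimated correlation; 12 adjusted over the list alone). Cytosolic ribosomal proteins had 13 of 33 lower (adjusted p = 0.00160, and adjusted p = 0.491 with an estimated correlation; 15 adjusted over the list alone), with RpS20 3.16-fold and RpL27 2.94-fold lower. Core clock genes had 5 higher and 1 lower of 8 (adjusted p = 0.0276, and adjusted p = 0.261 with an estimated correlation; 5 and 1 adjusted over the list alone), with tim at least 7.54-fold and per at least 5.40-fold higher, and the test was lost without adult Elav replicate 2 (0.0627). Pdf (0.89, SE 0.50) and Fer2 (0.58, SE 0.66) were not called. The comparison called 3352 genes, 1558 higher and 1794 lower in adults, and over all genes the groups did not overlap in 4017, where chance gives 10%. Without larval Elav replicate 3 there were 1567 higher and 1450 lower.

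The enrichment of Pdf over Elav cells was compared between stages as a difference of log2 differences. For large Pdf cells, Vmat had a difference of -15.66 (SE 1.46, adjusted p = 1.14e-06), and of -12.13 with values under 5 raised to 5. It lay below 5 on all large Pdf arrays and had means of 15.32 in adult Elav, 6.80 in larval Pdf and 3.17 in larval Elav cells. Fast transmitter and amine synthesis and transport had 10 of 14 lower (adjusted p = 7.65e-08, and adjusted p = 0.00564 with an estimated correlation; 10 adjusted over the list alone), and neuropeptides 11 of 22 (adjusted p = 3.39e-06, and adjusted p = 0.0204 with an estimated correlation; 14 lower and 1 higher adjusted over the list alone). The synaptic and pan-neuronal list had 13 of 17 lower (adjusted p = 7.19e-09, and 0.0806 with an estimated correlation, with 14 adjusted over the list alone). Its gene Rim stood at 11.91 in large Pdf, 11.85 in adult Elav, 11.46 in larval Pdf and 3.04 in larval Elav cells. Neuroblast and proliferation genes had 11 of 20 higher (adjusted p = 2.61e-08, and adjusted p = 0.103 with an estimated correlation; 13 adjusted over the list alone). For small Pdf cells, fast transmitter genes had 12 of 14 lower (adjusted p = 3.35e-09, and adjusted p = 0.00564 with an estimated correlation; 12 adjusted over the list alone) and neuropeptides 9 of 22 (adjusted p = 5.63e-06, and adjusted p = 0.0218 with an estimated correlation; 10 adjusted over the list alone). Fer2 had a difference of 2.47 (SE 0.93) for large and 1.07 (SE 0.99) for small cells, or 3.05 and 1.66 with values raised to 5, neither called. The differences called 1359 genes for large cells (525 higher, 834 lower) and 1175 for small cells (438 higher, 737 lower).

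For large cells 13 more lists passed with the preset correlation alone. All of them were lower, which is a statement on enrichment over Elav cells and not on levels in Pdf cells. Of all 16 lists that passed as lower for large cells, 15 had a higher median level in adult than in larval Elav cells, and 8 had a higher one in large than in larval Pdf cells. The median of the channels was 3.31 in larval and 9.16 in adult Elav cells, and 6.90 in larval and 8.73 in large Pdf cells. That of the core clock list was 4.51 and 7.67, and 11.83 and 12.47, and that of glia 3.75 and 3.47, and 6.49 and 3.47. Counts here are of genes called lower unless stated. The glial list had 3 of 14 (adjusted p = 0.0312, and adjusted p = 0.197 with an estimated correlation, with 3 adjusted over the list alone). Its test was lost with values under 5 raised to 5 (0.0824) and without larval Elav replicate 2 (0.0506), larval Pdf replicate 2 (0.0819) or adult Elav replicate 3 (0.0975). Hemocyte genes had 2 of 11 (adjusted p = 0.00813, and adjusted p = 0.357 with an estimated correlation, with 3 adjusted over the list alone). Photoreceptor genes had 8 of 20 (adjusted p = 2.76e-04, and adjusted p = 0.142 with an estimated correlation, with 9 lower and 1 higher adjusted over the list alone). Stress genes had 4 of 11 (adjusted p = 0.00217, and adjusted p = 0.120 with an estimated correlation, with 5 adjusted over the list alone). The core clock list had 2 of 8 (adjusted p = 0.0259, and adjusted p = 0.258 with an estimated correlation, with 5 lower and 1 higher adjusted over the list alone). This test was lost with values raised to 5 (0.0645) and without larval Pdf replicate 3 (0.0620) or adult Elav replicate 2 (0.0788). Clock neuron factors had 5 of 13 (adjusted p = 0.00209, and adjusted p = 0.102 with an estimated correlation, with 5 lower and 1 higher adjusted over the list alone). Peptide processing had 5 of 10 (adjusted p = 0.00461, and adjusted p = 0.138 with an estimated correlation, with 5 adjusted over the list alone). The cAMP list had 5 of 11 (adjusted p = 0.00513, and adjusted p = 0.125 with an estimated correlation, with 5 adjusted over the list alone). Neuropeptide receptors had 5 lower and 1 higher of 13 (adjusted p = 0.00655, and adjusted p = 0.258 with an estimated correlation, with 5 and 1 adjusted over the list alone). That test was lost with values raised to 5 (0.0855). Amine and metabotropic receptors had 7 of 12 (adjusted p = 3.28e-07, and adjusted p = 0.0505 with an estimated correlation, with 10 adjusted over the list alone). Ionotropic receptors had 10 of 15 (adjusted p = 3.66e-07, and adjusted p = 0.102 with an estimated correlation, with 14 adjusted over the list alone). Channels had 14 of 25 (adjusted p = 3.39e-09, and adjusted p = 0.0892 with an estimated correlation, with 16 adjusted over the list alone). Axon guidance and adhesion had 5 of 20 (adjusted p = 0.0470, and adjusted p = 0.371 with an estimated correlation, with 6 lower and 1 higher adjusted over the list alone). It was lost with values raised to 5 (0.0757) and after another quantile normalisation (0.0960). It was also lost without larval Elav replicate 2 (0.107), larval Pdf replicate 2 (0.0785) or 3 (0.0665), large Pdf replicate 1 (0.0730) or adult Elav replicate 1 (0.0682) or 2 (0.0575).

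For small cells most of these lists passed too, again with the preset correlation alone. Of all 12 lists that passed as lower for small cells, 11 had a higher median in adult than in larval Elav cells and 8 a higher one in small than in larval Pdf cells. Glial genes had 3 of 14 (adjusted p = 0.0242, and adjusted p = 0.188 with an estimated correlation, with 3 adjusted over the list alone). The glial test was lost with values raised to 5 (0.0744) and without larval Pdf replicate 2 (0.0615) or adult Elav replicate 3 (0.0859). Hemocyte genes had 1 of 11 (adjusted p = 0.00295, and adjusted p = 0.285 with an estimated correlation, with 5 adjusted over the list alone). Photoreceptor genes had 6 of 20 (adjusted p = 0.00159, and adjusted p = 0.197 with an estimated correlation, with 6 adjusted over the list alone). Stress genes had 2 of 11 (adjusted p = 0.00461, and adjusted p = 0.157 with an estimated correlation, with 2 adjusted over the list alone). The synaptic and pan-neuronal list had 11 of 17 (adjusted p = 1.30e-09, and adjusted p = 0.0662 with an estimated correlation, with 13 adjusted over the list alone). Channels had 12 of 25 (adjusted p = 1.66e-08, and adjusted p = 0.102 with an estimated correlation, with 13 adjusted over the list alone). Ionotropic receptors had 10 of 15 (adjusted p = 7.71e-07, and adjusted p = 0.107 with an estimated correlation, with 11 adjusted over the list alone). Amine and metabotropic receptors had 6 of 12 (adjusted p = 1.95e-05, and adjusted p = 0.0864 with an estimated correlation, with 7 adjusted over the list alone). Peptide processing had 7 of 10 (adjusted p = 1.08e-04, and adjusted p = 0.0637 with an estimated correlation, with 8 adjusted over the list alone). The cAMP list had 2 of 11 (adjusted p = 0.0185, and adjusted p = 0.197 with an estimated correlation, with 6 adjusted over the list alone). The cAMP test was lost without larval Pdf replicate 3 (0.0567) or small Pdf replicate 2 (0.0569). Neuroblast and proliferation genes went the other way, again from the larval fall, with 11 of 20 higher (adjusted p = 2.61e-08, and 0.103 with an estimated correlation, with 14 adjusted over the list alone).

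Calls shared by larval and adult Pdf cells were counted, the stages having separate Elav controls. Larval and large Pdf cells shared 70 higher genes, where independent lists would share 34.6, and 68 lower genes against 55.4. In opposite directions, 77 were higher in larval and lower in large Pdf cells against 57.5, more than were higher in both, and 22 went the other way against 33.3. Larval and small Pdf cells shared 111 higher genes against 36.3 and 59 lower genes against 50.7, with 57 (52.6) and 22 (35.0) in opposite directions. Across genes, which are not independent replicates, the fold changes correlated with r = 0.03 and 0.11. In all 3 Pdf comparisons 51 genes were higher, among them Pdf, tim, vri, cry, per, Clk, Irk1, Hr51, Fkbp14 and Fer2, and 25 were lower. With shared controls the overlaps were larger. Larval Pdf and Tim without Pdf shared 517 higher genes (149 from independent lists) and 751 lower genes (249), and large and small Pdf cells 106 (9.32) and 223 (22.5). Simulated unchanged groups shared 0.02 calls on average in 50 draws, but with no gene changed few can pass, so this decides nothing. The covariance of fold changes was 2.95 for the larval pair and 1.44 for the adult pair, where shared controls alone gave 0.28 in simulation. With 3 controls no split leaves 2 in each part, so shared controls may give some of the excess.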

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

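The tests of other splits of the arrays were planned, and the tests of detected probe sets were chosen after the results were seen.

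The enrichment of Pdf over Elav cells differed between larvae and adults in 1359 genes for large and 1175 genes for small Pdf cells, by the limma test of the difference itself. Undetected values enter these differences at the level of the background model, so each is followed in brackets by the difference with values under 5 raised to 5. For large cells the log2 difference was 8.13 (6.29) for Orc1, 7.13 (6.23) for Pex7, 7.21 (6.19) for CG12496, 7.02 (6.05) for CG14075 and 8.58 (about 6) for mael. It was -15.86 (-13.96) for CG12239, -12.95 (-12.26) for Arc1, -15.66 (-12.13) for Vmat, -14.17 (-11.70) for Scp2 and -13.10 (-11.43) for ITP. For small cells it was 10.92 (6.94) for CG15646, 6.96 (6.23) for Pex7, 7.17 (6.19) for CG12496, 8.44 (5.82) for CG14545 and 7.36 (5.65) for CG9993. At the other end it was -17.04 (-14.43) for CG12239, -15.24 (-11.83) for ImpL2, -13.87 (-10.97) for Gad1, -12.57 (-10.41) for Ms and -10.66 (-10.36) for ITP. The Elav baseline moved in several of these genes, as Vmat stood at 15.32 in adult and 3.17 in larval Elav cells, and Pex7 at 2.17 and 12.02.

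Of 100 drawn splits of the arrays within each stage, 2 gave at least the 1359 genes of the large Pdf difference, the real split included. The other one exchanged the larval Pdf and Elav groups, which keeps all groups intact, and called 1682 genes. The next highest called 1088. Splits that mix Pdf and Elav arrays put the differences between the groups into the spread and call fewer genes for that reason, so the share says nothing on chance. For the comparisons of 3 with 3 arrays the 10 possible splits are too few for a share under 0.05. In each of them 1 split, the real one, reached the count, and the highest other split gave 21 genes against 1996 for larval Pdf, 4 against 1795 for larval Tim, 40 against 3075 for Tim without Pdf, and 10 against 1740 for larval Pdf against Tim without Pdf. It gave 5 against 695 for large Pdf cells, 8 against 3063 for the eye and 2 against 3352 for adult against larval Elav cells.

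The proliferation list was higher in larval Elav than in larval Pdf, larval Tim and Tim without Pdf cells with the preset correlation, and lost this with an estimated one (adjusted p = 0.102, 0.103 and 0.0556). More detected probe sets on the larval Elav arrays is argued against for larval Pdf and larval Tim cells, since the larval Elav arrays had fewer, by -2.46 and -3.27 percentage points (SD at most 1.96). Against Tim without Pdf, -0.744 lay within the spread and decides nothing. The median level of the list was 12.14 in larval Elav, 9.03 in larval Pdf, 9.46 in larval Tim and 6.35 in Tim without Pdf cells, with 20, 19, 20 and 11 of its 20 genes above 5 in the mean. Its RNA was detected in the larval sorts, but its source in dividing or newly born cells and differences of cell type remain open and untested.

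Probe sets outside the gene comparisons also differed. Of 1284 tested probe sets matched to no gene or to several, 247 were called for larval Pdf, 86 for large Pdf and 95 for small Pdf against Elav cells. Within groups of 2 or 3 arrays no test of single outlying values was made.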

How the results depend on the processing

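Only the 3' bias index as a covariate and the fit without the 2 least correlated arrays were chosen after seeing the data. No called named gene reversed direction under any alternative, and every setting fixed beforehand was run. The balance of higher and lower calls did turn. For larval Pdf against Elav (1017 higher, 979 lower) it turned after another quantile normalisation (981 and 1069), with values under 5 raised to 5 (862 and 1057), with the mean of probe sets (967 and 988), with array weights (1176 and 1505) and without larval Elav replicate 1 (880 and 1084). For larval Tim against Elav it turned with array weights (1613 and 1789), for adult against larval Elav without larval Elav replicate 3 (1567 and 1450), and for large against small Pdf without large Pdf replicate 2 (55.1% higher) or small Pdf replicate 1 (54.3%) or 2 (50.2%). Centring each array turned it in 6 comparisons. Centring moves all genes of an array alike, so the shares of rises under it follow from the centring and test nothing.

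Counts of called genes stayed within 1.5 times those reported, except in the following cases. With only the groups compared in the fit, larval Pdf against Elav gave 1173, larval Pdf against Tim without Pdf 868, large Pdf 426, small Pdf 352 and large against small Pdf 19, where the fit has fewer arrays to estimate the spread. With array weights larval Tim against Elav gave 3402. With the 3' bias index Tim without Pdf gave 1604, larval Pdf against Tim without Pdf 719 and the eye 1577. Without the 2 least correlated arrays (Tim without Pdf replicate 3 and larval Pdf replicate 1) larval Pdf against Tim without Pdf gave 1068. The cause was not tested for array weights and the index, and the last fit has fewer arrays.

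Leaving out each replicate gave 1294 to 1964 calls for larval Pdf against Elav, 1205 to 1699 for larval Tim, 2348 to 3066 for Tim without Pdf and 1145 to 1537 for larval Pdf against Tim without Pdf. It gave 471 to 663 for large Pdf, 408 to 573 for small Pdf, 197 to 292 for large against small, 2259 to 2903 for the eye and 2870 to 3141 for adult against larval Elav. The differences of differences gave 1006 to 1372 for large and 861 to 1245 for small Pdf cells. Counts moved by over 1.5 times without larval Elav replicate 2 (1294), Tim without Pdf replicate 3 (1145) and small Pdf replicate 1 (408). Without small Pdf replicate 1 or 2, the lone small Pdf array is assumed to vary like the other groups.

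With the replicate number as a block the counts were 1912, 1708, 2991 and 1648 for the larval comparisons in the order above, 614 for large Pdf, 619 for small Pdf, 240 for large against small, 2974 for the eye, 3293 for adult against larval Elav, and 1279 and 1100 for the differences of differences. Arrays with the same number did not deviate together. Of 25 pairs 2 had a correlation over 0.1, the range was -0.32 to 0.17, and in 0 comparisons did every pair exceed 0.1, so the numbers do not pair the samples.

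Of 601 pairs of a named gene and a comparison, the call was lost for 89 with only the groups compared, 39 with the 3' bias index, 33 with values under 5 raised to 5, 20 without a filter, 16 without the 2 arrays, 9 under the block, 8 after another quantile normalisation, 8 with the mean of probe sets, 6 with centring and 2 with trend and robust settings. Leaving out each replicate lost 221 of 4273 such calls. Of 264 list tests, the estimated correlation lost 94, values raised to 5 lost 10 and gained 4, another quantile normalisation lost 7 and gained 3, and the block lost 1 and gained 4. With fry, which tests for a shift in 1 direction without reference to the other genes, 2 fewer and 31 more passed. Leaving out replicates lost 37 and gained 32 of 1800. Signal over background limits the folds of genes undetected in 1 group, which are bounds.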

Other observations

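The tests of ring gland cells, 3' bias and scaling were chosen after the results were seen, and so was the index of 3' bias.

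The eye differed from adult Elav cells in genes outside the lists. The immune-induced peptide gene BomS6 was at least 447-fold higher (adjusted p = 1.77e-13; 13.80 ± 0.73 against 3.93 ± 0.37, SD, n = 3), and BomS2 stood at 13.88 ± 0.65 against 4.87 ± 0.82. The metallothionein gene MtnA stood at 14.20 ± 0.30 against 4.71 ± 0.49, and rtp, which encodes retinophilin of photoreceptors, was at least 438-fold higher. The small heat shock gene Hsp26 was lower, at 5.06 ± 1.37 against 13.69 ± 0.88 (adjusted p = 5.11e-07), and CG8401 was at least 943-fold lower.

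The levels of 2 genes were set beside those of Pdf across stages. Irk1, an inward rectifier potassium channel gene, stood at 10.33 ± 0.84 in larval Pdf, 10.92 ± 0.35 in large and 12.17 ± 0.35 in small Pdf cells (SD, n = 3, 3 and 2), against 3.23 ± 0.29 in larval and 4.98 ± 1.52 in adult Elav cells. The PDF receptor gene Pdfr did not follow Pdf, as it was above 5 in the means of larval Pdf (7.27) and small Pdf cells (6.59) and lay at 2.44 in large Pdf cells, 2.38 in larval Tim cells and 2.36 in Tim without Pdf.

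Several genes of hormone synthesis were high in larval Tim cells with and without the PDF neurons. In larval Elav, Pdf, Tim and Tim without Pdf, spok had means of 2.52, 2.48, 9.89 and 12.82, phtm of 2.11, 2.29, 11.44 and 12.12, and jhamt of 2.37, 2.35, 12.33 and 14.04. RNA from the gland in every larval dissection is argued against, since the highest value of 9 hormone synthesis genes on the 6 larval Elav and Pdf arrays was 4.51. A candidate explanation is that ring gland cells carried the Tim reporter and passed the sort. Gland cells without the reporter could also have been carried along, and the markers cannot tell these apart. Among 16 ring gland markers, 10 had not been among the named genes. Their median difference between Tim without Pdf and Pdf cells was 5.55 log2 units, and 8 of these 10 were called higher. Over all 16 the count was 14, but named markers add no evidence. Against this, ecd was called lower in Tim without Pdf (6.36 against 8.04), and Akh, of the corpora cardiaca, stayed at 2.01 there. In larval Tim cells Akh stood at 5.87 ± 6.54 (SD, n = 3). Of the 16 markers, 4 (Npc1a, mld, ecd and Start1) were also above 5 in larval Elav cells. They do not exclude gland RNA there.

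More genes fell than rose against Elav cells in Tim without Pdf (36.6% rises), the eye (36.1%), large Pdf (37.6%) and small Pdf cells (40.8%). For large and small Pdf cells stronger 3' bias is argued against, since their index differed from that of adult Elav by -0.0508 and -0.0793 (SD at most 0.221 and 0.383), and with the index in the fit the shares were 37.2% and 41.5%. For Tim without Pdf and the eye, whose index was higher than in Elav cells (3.43 against 1.70 and 3.92 against 2.42), the shares with the index in the fit were 42.3% and 47.7%. The median of all genes moved less, from -0.23 to -0.17 and from -0.50 to -0.41. As the index goes with these 2 groups, 3' bias cannot be told apart there from a true excess of falls. After another quantile normalisation the shares were 43.4% for Tim without Pdf, 46.5% for the eye, 47.2% for large and 47.0% for small Pdf cells, so the scaling between arrays may account for much of the excess in the last 3. Forcing the arrays to 1 distribution can also remove a true excess of falls, so this stays open. Differences of cell type and tissue remain open and untested.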
